A study of Mus musculus with 2 samples.

How the data were processed

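The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) for H3K27me3, the histone mark laid down by Polycomb repressive complex 2 and found at silenced developmental genes. The tissue was the embryonic facial prominence of B6NCrl mouse embryos at embryonic day 12.5. There was 1 group with 2 biological replicates. Replicate 1 pooled 120 embryos and replicate 2 pooled 88 embryos, each of mixed sex.

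The authors deposited 4 peak lists on the mm10 genome build: 1 for each replicate, 1 called on both replicates pooled, and 1 of replicated peaks. Every replicated peak was also a peak of the pooled list. In each deposited list the signal value is a fold enrichment, a ratio, and what it is relative to is not stated beyond a control in the labels. The deposited lists also give a −log10 p and a −log10 q for each peak, computed by the peak caller of the authors. The smallest −log10 p was just above 2 in every list. The peak caller and the aligner are not given in the sources used here. The list of replicate 1 was derived from its own alignments and 1 further file, and that of replicate 2 from its own alignments and 2 further files, whose roles are not stated. The peak lists hold no read counts, so the depth of each library is unknown here and no counting interval is given.

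Gene positions came from GENCODE mouse release M21 on GRCm38, the same assembly as mm10. Coding genes on chromosomes 1 to 19 and X were used, 21755 records in all. The 54 records whose symbol occurred more than 1 time were reduced to 21728 genes with distinct symbols. A gene was called marked when a replicated peak lay, by at least 1 bp, within 1 kb of its 5′ end. For each gene the share of the 10 kb around its 5′ end covered by peaks was also computed. The mean and SD of that share are over the 2 replicate lists. Promoter CpG density was the observed over expected CpG ratio within 1 kb of the 5′ end, and CpG-rich promoters were those in deciles 6 to 10 of it. The ungapped genome measured 2559.44 Mb, counting as gaps the runs of unknown bases of at least 1000 bp.

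There is no second group, so the comparisons are between the replicates, between gene groups and between regions within the lists. Genes, peaks and regions are not independent replicates, and every p describes genes or regions within 1 tissue. Overlap between the replicates was set beside 100 random placements of the peaks within their chromosomes. Each of 20 gene lists was compared with all other coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists. Beside it stood 10000 random lists of the same size, drawn to match the list on the decile of promoter CpG density. Facial and neural factor lists were compared by two-sided Fisher's exact tests, adjusted over both comparisons. The 4 Hox clusters were each set beside 1000 random intervals of the same length on the same chromosome, so the smallest p possible was 0.001, for a one-sided question of higher coverage. Domains were formed by joining replicated peaks at most 3 kb apart. The threshold for every test was 0.05.

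The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The 20 lists were Hox genes, broadly used facial transcription factors, regional facial transcription factors, face epithelium genes, neural transcription factors, neuron differentiation genes, heart and lateral mesoderm factors, endoderm factors, blood and endothelial factors, muscle regulators, skeleton genes, Wnt ligands, fibroblast growth factors, bone morphogenetic protein signals, cyclin-dependent kinase inhibitors, Polycomb genes, housekeeping genes, olfactory receptors, vomeronasal receptors, and terminal products. The terminal products were those of liver, blood, pancreas, muscle and skin. All listed genes were measured except 1 of the 28 terminal products. The 18 lists other than the receptor families held 448 genes, 4 of them in more than 1 list. The rule named, for each list, up to 3 marked members with the largest replicated coverage of the 10 kb around the 5′ end and up to 2 unmarked members in order of symbol. It also named the genes held in the 20 largest domains, any Hox gene without the mark, and any member of the facial factor lists. Other genes are named only where it is said that they were chosen after their values were seen.

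The alternatives were a window of 2.5 kb on either side, at least 50% of the window covered, replicated peaks at −log10 q of 5 or more, the pooled list, any coding transcript start, CpG-rich promoters only, each replicate left out, a reciprocal overlap of 50%, equal list lengths, and joining distances of 1 kb and 10 kb. Tests were run on simulated data before use. Peaks were planted within the window of 200 isolated gene starts, and all 200 of 200 genes were recovered, which checks the counting only. Lists of 20 genes with 60% marked were called in 97% of 1000 simulations, and unchanged lists in 1.5% of 1000. The simulated genes were drawn at random and marked independently, so these rates do not cover lists of neighbouring genes. Marks were also simulated from the CpG decile alone, for 200 lists of 60 genes drawn from deciles 5 to 8. Of these lists, 45% passed Fisher's exact test without adjustment. Matched draws were therefore made for each of the 20 lists and for the gene families. The 2.5% that rose above the matched lists is the share set by the cut, so it checks the code only. Most lists used here were smaller, and neither share is their error rate. Overlap counts were checked against bedtools. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1, with random seed 11. Alignments and signal tracks were not used here, and no peak on chromosome Y was present in any list.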

Results

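H3K27me3 was mapped by ChIP-seq in the embryonic facial prominence, the tissue that forms the jaws, nose and lips, of mouse embryos at embryonic day 12.5. There was 1 group with 2 biological replicates, pools of 120 and 88 embryos of mixed sex. Replicate 1 had 73355 peaks and replicate 2 had 99718. The pooled list had 123938 peaks, of which 33910 made up the replicated list. Of these replicated peaks, 6983 overlapped a peak of only 1 replicate list and 291 overlapped none, by at least 1 bp. The replicated peaks covered 30.5 Mb, or 1.19% of the ungapped genome, with a median width of 492 bp and a median fold enrichment of 2.97. The widest was 30323 bp, and 664 were 5 kb or wider. Depth is unknown from the peak lists. All positions are on mm10, and errors are SD over n = 2 replicate lists unless stated.

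The strong H3K27me3 regions of the face were shared by both pools, and the weak ones were mostly seen in a single pool. Of the replicate 1 peaks, 48.6% overlapped a replicate 2 peak, against 3.29% ± 0.0799 (SD over 100 random placements). Of the replicate 2 peaks, 32.4% overlapped a replicate 1 peak, against 2.21% ± 0.0499 at random. The shared bases made up 34.6% of all bases covered in either replicate, against 0.736% at random. Among peaks at −log10 p of 10 or more, 99.1% of 5978 in replicate 1 and 97.1% of 7068 in replicate 2 overlapped the other replicate. Among peaks at −log10 p from 3 to 5, the shares were 33.9% and 19.2%. Peaks seen in replicate 1 alone numbered 37721 and had a median fold enrichment of 2.67. Those seen in replicate 2 alone numbered 67391 and had a median of 2.62, and only 205 of them reached −log10 p of 10. In promoters lay 3.53% and 3.58% of these peaks, by midpoint. Across 28727 pairs of mutual best partners, fold enrichment had a Spearman rho of 0.513 and a Pearson r of 0.722, values across peaks, which are not independent replicates. With a reciprocal overlap of 50% the shares of all peaks fell to 22.6% and 16.6%, and with peaks at −log10 q of 5 or more in both lists they were 78.1% and 57.0%.

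**Figure D1:**
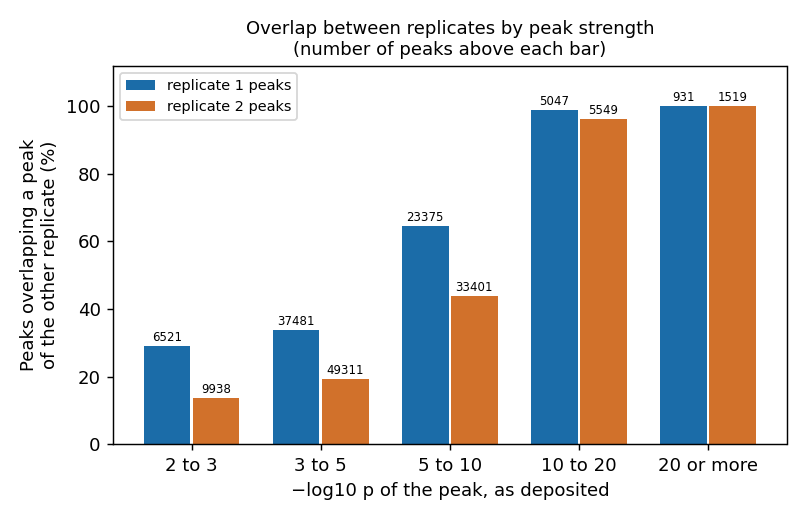
Percent of peaks of each replicate that overlap a peak of the other replicate by at least 1 bp, by bins of −log10 p of the peak. The share reaches 100% in both replicates at −log10 p of 20 or more and is 29.2% (replicate 1) and 13.7% (replicate 2) in the weakest bin.

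H3K27me3 was concentrated at gene starts. Promoters, taken as 1 kb on either side of the 5′ end of coding genes, held 15.4% of replicated peak bases and 1.60% of the genome, a ratio of 9.64. The separate replicate lists had 12.5% ± 1.07 of their bases there. Exons of coding genes outside promoters held 10.2% of the bases against 3.37% of the genome. Introns held 35.2% against 36.2%, and intergenic sequence held 39.2% against 58.8%. No test was applied to these shares.

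The mark lay at the start of 3887 of 21728 coding genes, or 17.9%. A peak covered the start itself in 2401 of them, or 61.8%. The replicate lists marked 3772 genes in common, with 620 more in replicate 1 alone and 1246 more in replicate 2 alone. Of the 3887 marked genes, 3585 were also marked in both replicate lists, 280 in 1 of them and 22 in neither. Marked genes were rare among promoters poorest in CpG, with 25 of 2173 genes in the lowest decile, and most frequent in the fifth decile, at 32.2%. In the highest decile 14.4% of genes were marked. When at least 50% of the window had to be covered, 2374 genes were marked.

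All 39 Hox genes, the homeobox genes that set position along the body axis, carried the mark. Facial mesenchyme is known to be largely free of Hox expression. The share was 100% against 17.7% of other coding genes (two-sided Fisher's exact test, adjusted p = 4.04e-29), and random lists matched on CpG density averaged 23.3%. Both comparisons treat the 39 genes as separate, though they lie in 4 clusters and are not independent. The 10 kb around Hoxc4 was covered to 99.4% ± 0.0354, that around Hoxb5 to 97.7% ± 0.0778 and that around Hoxb3 to 96.7% ± 2.14. The Hoxa cluster (chromosome 6, 52155590 to 52260880) was covered to 93.8% by replicated peaks and 88.4% ± 2.98 in the replicate lists. The Hoxc cluster (chromosome 15, 102921103 to 103036852) was covered to 97.9%, and 95.7% ± 1.04 in the replicate lists. The Hoxd cluster (chromosome 2, 74668310 to 74765142) was covered to 93.0%, and 86.7% ± 3.94 in the replicate lists. The Hoxb cluster (chromosome 11, 96194316 to 96368256) was covered to 79.6%, and 77.2% ± 2.52 in the replicate lists. Each cluster exceeded all 1000 random intervals of its length on its chromosome, giving a permutation p = 0.001, the smallest that the draws allow. A few random intervals lay on the cluster itself, 3 for Hoxa and 5 for Hoxb. The highest of those off the cluster was covered to 27.8% for Hoxa, 38.7% for Hoxb, 41.7% for Hoxc and 45.7% for Hoxd.

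**Figure D2:**
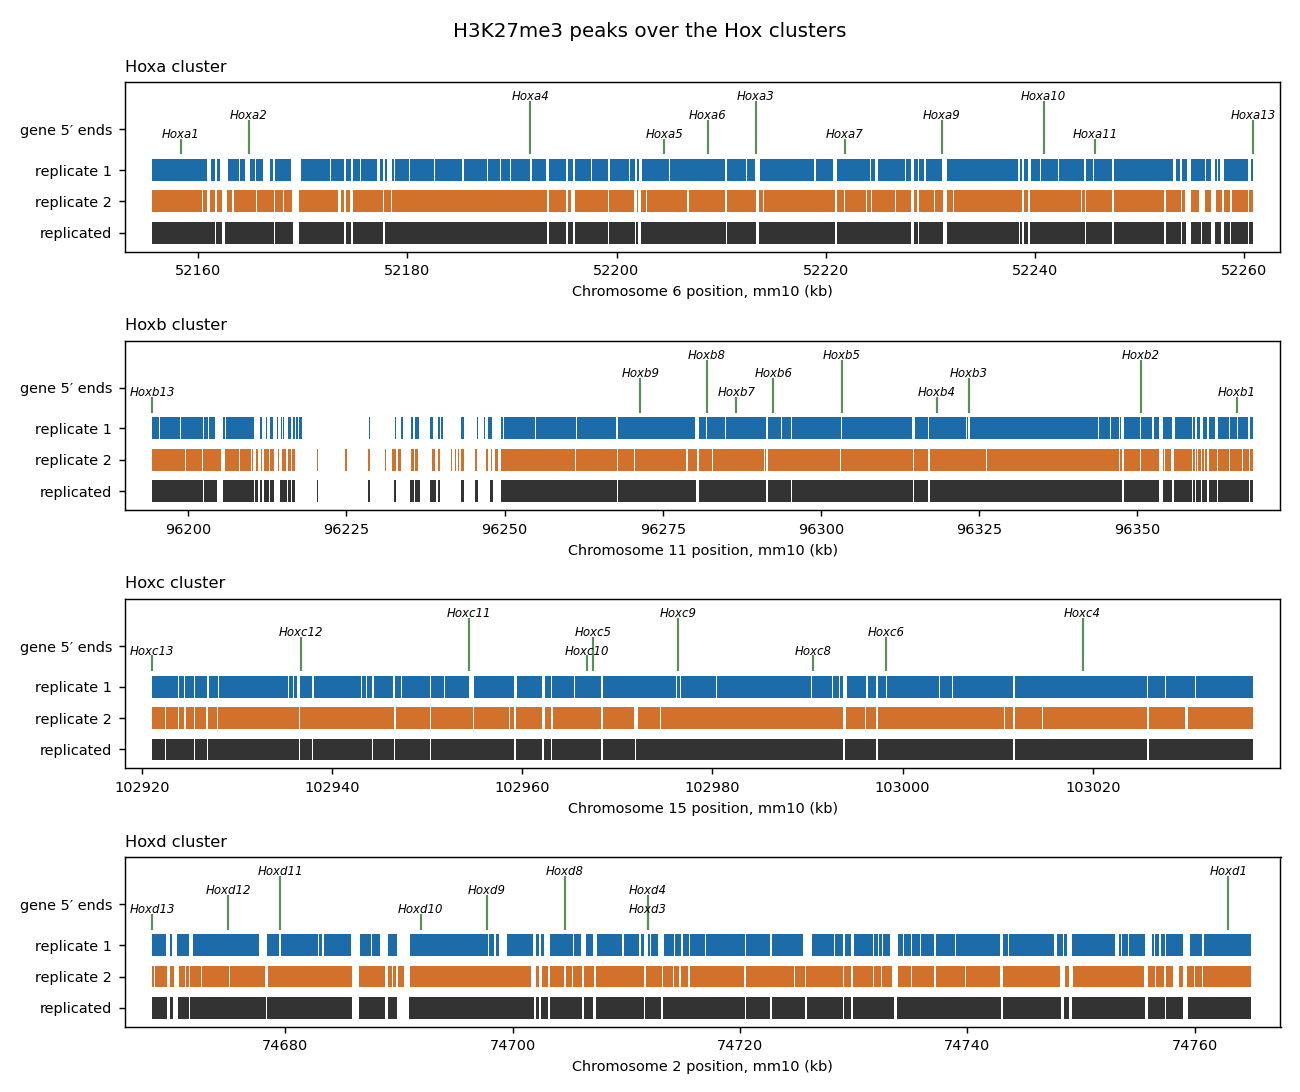
Maps of the 4 Hox clusters on mm10, with position on the horizontal axis, peaks of each list as bars and gene 5′ ends as ticks. Replicated peaks cover 93.8% (Hoxa), 79.6% (Hoxb), 97.9% (Hoxc) and 93.0% (Hoxd) of the clusters.

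Transcription factor genes listed for a single part of the face were marked nearly throughout. Those listed as used across facial mesenchyme divided into marked and unmarked genes. The lists were set beforehand, and expression was not measured here. Of 32 regional factors 29 were marked, or 90.6%. Among them Hand1, a factor of the distal lower jaw (chromosome 11, 57832818), had 87.9% ± 5.10 of its surrounding 10 kb covered. Pitx1, a factor of the lower jaw and hindlimb (chromosome 13, 55836192), had 83.1% ± 0.0141, and Pax9, needed for teeth and palate (chromosome 12, 56691767), had 79.8% ± 5.08. Of 20 broadly used factors 11 were marked, or 55%, with Tfap2a at 79.9% ± 6.51 (chromosome 13, 40738376), Msx2 at 50.5% ± 2.02 and Msx1 at 43.8% ± 5.35. Unmarked were Meis1, Meis2, Nr2f1, Prrx1, Prrx2, Six1, Snai2, Sox9 and Tcf4. Around the starts of Prrx2, Snai2 and Tcf4 no peak of either replicate lay within the 10 kb, and Prrx1, a factor of limb and facial mesenchyme, had 8.25% ± 5.11. Both lists exceeded other coding genes by two-sided Fisher's exact test, with adjusted p = 2.19e-18 for regional and 0.000288 for broadly used factors. The share of regional factors exceeded that of broadly used factors by 35.6 percentage points (two-sided Fisher's exact test, p = 0.00560, adjusted over 2 tests 0.00560). Osr2, Tbx2 and Tbx22 were the unmarked regional factors. Osr2 and Six1 were marked in both replicate lists but not in the replicated list, and Nr2f1, Tbx2 and Tbx22 in replicate 2 alone. With at least 50% of the window covered the broadly used factors fell to 20.0% (Fisher's exact test, adjusted p = 0.314). They rose to 70.0% with the pooled list and to 70.0% with any coding transcript start. Some of the unmarked calls thus depend on the peak list and the gene start used.

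**Figure D3:**
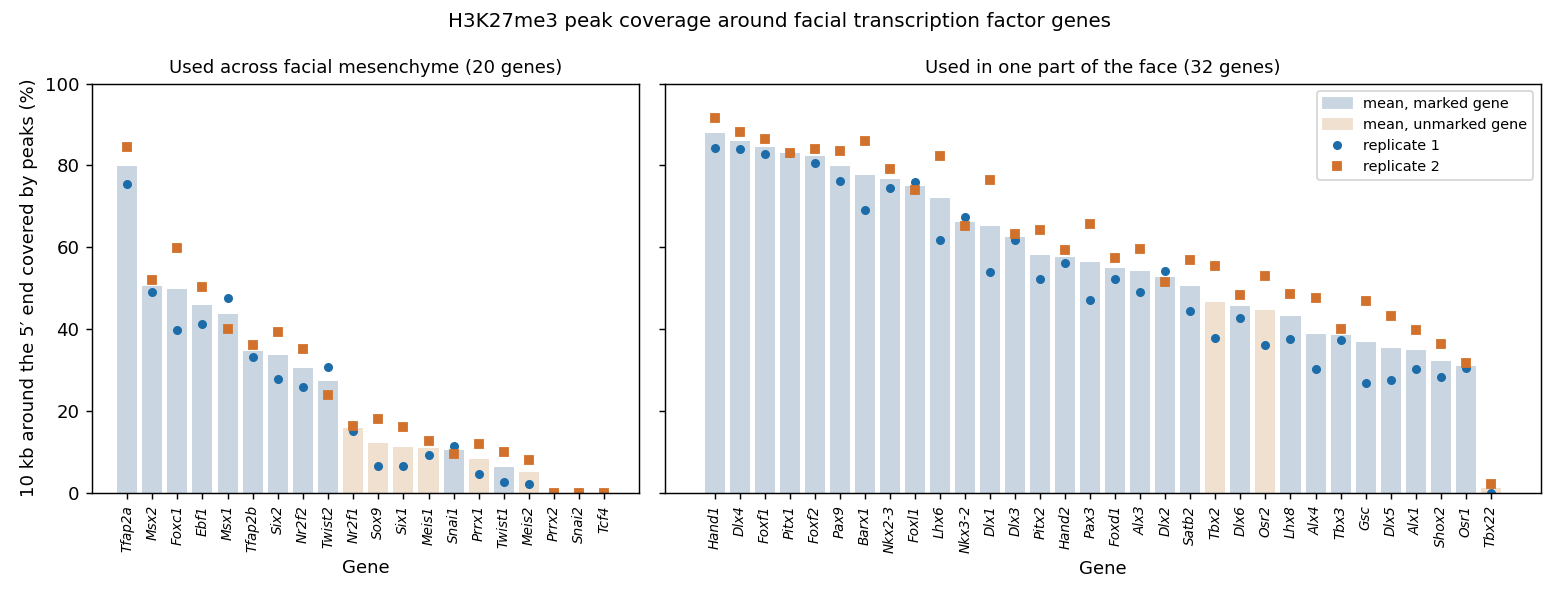
Percent of the 10 kb around the 5′ end covered by peaks for each broadly used and regional facial transcription factor gene, with bars for the mean of the 2 replicate lists, coloured by whether the gene is marked, and a point for each replicate. Hand1 stands at 87.9% and Tfap2a at 79.9%, while Prrx2, Snai2 and Tcf4 lie at 0.

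Neural transcription factor genes, which direct neuron formation in brain and ganglia, were marked in 60 of 62 cases, or 96.8%. Coverage of the surrounding 10 kb was 97.2% ± 2.18 for Mnx1, a motor neuron factor, 96.4% ± 1.96 for Lhx5 and 93.0% ± 5.63 for Nkx6-2. The unmarked genes were Neurod4, at 1.83% ± 0.120, and Pou3f3, at 39.0% ± 5.64 and marked in both replicate lists. The list exceeded other genes by two-sided Fisher's exact test (adjusted p = 1.27e-41). The broadly used facial factors were marked less often than neural factors, by a difference of −41.8 percentage points (two-sided Fisher's exact test, p = 2.35e-05, adjusted p = 4.70e-05). For the regional facial factors the difference was −6.15 points, which did not pass the test (two-sided Fisher's exact test, p = 0.333, adjusted p = 0.333). That difference turned to 1.61 points with the pooled list and 0.101 points with any transcript start, neither past the threshold. It was −1.51 points without replicate 1 and −4.64 points without replicate 2, and was −21.6 points with at least 50% of the window covered (Fisher's exact test, adjusted p = 0.0178).

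Genes of the heart, endoderm, blood and muscle regulator lists were marked in most cases. Of heart and lateral mesoderm factors 13 of 14 were marked, or 92.9%, with Tbx5, a heart and forelimb factor (chromosome 5, 119832668), covered to 90.8% ± 6.14, Irx4 to 87.5% ± 4.98 and Wt1 to 84.8% ± 6.79. Mef2c was the exception, with 0 covered. Of endoderm factors 16 of 20 were marked, or 80.0%, led by Cdx2, a hindgut factor, at 97.0% ± 0.0566, Foxa2 at 94.1% ± 1.75 and Onecut1 at 91.2% ± 11.6, while Foxn1 and Hnf1a were unmarked. Of blood and endothelial factors 15 of 20 were marked, or 75%, with Gata2 at 93.5% ± 6.49, Tal1 at 82.1% ± 7.5 and Pax5 at 81.9% ± 5.51. Gata1, the erythroid factor, and Cebpe were unmarked. With at least 50% of the window covered the blood and endothelial share fell to 45.0%, against 10.9% of other genes. Of muscle regulators 6 of 10 were marked, or 60%, with Pax7 at 83.9% ± 2.18, Myod1 at 74.7% ± 8.17 and Msc at 57.7% ± 4.14, while Mef2a and Mef2d were unmarked. Fli1, a blood and endothelial factor chosen after its values were seen, counts as marked but was marked in neither replicate list. Also chosen after their values were seen, the further unmarked members were Hnf4a and Nr1h4 for endoderm, Spi1, Runx1 and Lmo2 for blood, and Myog and Six4 for muscle. By two-sided Fisher's exact test the adjusted p was 4.99e-09 for the heart list, 4.99e-09 for endoderm, 6.24e-08 for blood and 0.00443 for muscle. Among CpG-rich promoters alone the muscle list held 7 genes, 4 of them marked, and its Fisher's exact test no longer passed (adjusted p = 0.0615).

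Signalling genes were marked as well. Of the Wnt ligands 18 of 19 carried the mark (94.7%, two-sided Fisher's exact test, adjusted p = 1.79e-12). Wnt10a, which acts in teeth and skin, was covered to 96.8% ± 0.990, Wnt10b to 95.9% ± 0.841 and Wnt6 to 86.0% ± 7.54. The unmarked ligand was Wnt5a, which acts in outgrowth of the face and limbs, at 9.10% ± 0.983. Of the bone morphogenetic protein signals 16 of 20 were marked (80.0%, Fisher's exact test, adjusted p = 4.99e-09), with Gdf7 at 86.4% ± 4.43, Bmp6 at 55.7% ± 1.76 and Gdf6 at 53.4% ± 1.2, and Bmp10 and Bmp5 were unmarked. With at least 50% of the window covered their share fell to 45.0%, against 10.9% of other genes. Of the fibroblast growth factors 14 of 22 were marked (63.6%, Fisher's exact test, adjusted p = 3.89e-06), with Fgf3 at 84.9% ± 4.02, Fgf8 at 83.7% ± 4.82 and Fgf11 at 60.4% ± 11.6, and Fgf10 and Fgf12 were unmarked. Of 7 cyclin-dependent kinase inhibitor genes, which halt the cell cycle, 5 were marked (71.4%, Fisher's exact test, adjusted p = 0.00371). Cdkn2a was covered to 79.3% ± 0.926, Cdkn2b to 64.7% ± 2.22 and Cdkn1a to 33.8% ± 5.43, and Cdkn1b and Cdkn2d were unmarked. Chosen after their values were seen, Gdf5 and Grem2 were the further unmarked bone morphogenetic protein signals, and Cdkn1c and Cdkn2c the further marked kinase inhibitors. The call for the kinase inhibitors ended with peaks at −log10 q of 5 or more (42.9%, Fisher's exact test, adjusted p = 0.0784) and with at least 50% of the window covered (28.6%, adjusted p = 0.216).

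The lists of epithelium and neuron differentiation genes were marked more often than other coding genes. The lists of the skeleton and of terminal products did not pass the test. Of 24 genes of surface and oral epithelium 19 were marked (79.2%, two-sided Fisher's exact test, adjusted p = 2.92e-10), with Wnt10a, Pkp1 at 84.5% ± 0.551 and Ovol1 at 82.5% ± 5.50, while Krt14 and Krt15 were unmarked. This list mixes regulators and signals, such as Ovol1 and Wnt10a, with structural genes such as keratins. Of 24 neuron differentiation genes 17 were marked (70.8%, Fisher's exact test, adjusted p = 3.32e-08), with the transmitter genes Slc32a1 at 91.1% ± 1.99, Gad2 at 87.0% ± 1.70 and Chat at 73.6% ± 0.431, while Dcx and Elavl4 were unmarked. Of 23 cartilage, bone and tooth genes 7 were marked (30.4%, against 18.5% in matched lists, Fisher's exact test, adjusted p = 0.185), with Comp at 70.3% ± 1.12, Acan at 66.2% ± 0.969 and Sox6 at 45.1% ± 1.48, while the enamel genes Ambn and Amelx were unmarked. Of 27 terminal products of liver, blood, pancreas, muscle and skin 5 were marked (18.5%, against 12.4% in matched lists, Fisher's exact test, adjusted p = 1), with Acta1 at 69.4% ± 9.04, Ckm at 47.1% ± 2.57 and Lor at 41.4% ± 6.21, while Actc1 and Afp were unmarked. Chosen after their values were seen, Trp63, Krt5 and Krt19 were the further unmarked epithelial genes, and Cela1 and Myh7 the further marked terminal products. The skeleton list passed the threshold without replicate 1 (43.5%, Fisher's exact test, adjusted p = 0.0296), with the pooled list (47.8%, adjusted p = 0.0304) and among CpG-rich promoters (4 of 5 genes, adjusted p = 0.0149).

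Olfactory and vomeronasal receptor genes were almost never marked, whereas the Polycomb and housekeeping lists did not pass Fisher's exact test in either direction. Of 29 Polycomb genes 4 were marked (13.8%, against 19.6% in matched lists, two-sided Fisher's exact test, adjusted p = 0.850), among them Cbx4 at 58.5% ± 11.1, Cbx8 at 55.8% ± 0.474 and Phf19 at 45.4% ± 6.76, while Aebp2 and Bmi1 were unmarked; the fourth marked gene was Pcgf5, chosen after its values were seen. Of 40 housekeeping genes 3 were marked (7.5%, Fisher's exact test, adjusted p = 0.116), and random lists matched on CpG density averaged 21.4% (adjusted p over the lists 0.0395). Actb and Atp5b were unmarked. The marked ones were Pgk1 and Nono, both on X and with 4.34% ± 2.26 and 4.12% ± 1.31 of the 10 kb covered, and Rpl3 at 50.1% ± 10.3. The start of Rpl3 (chromosome 15, 80091868) lies beside that of Syngr1 (80091334), a synaptic vesicle gene chosen after its values were seen, which was also marked. Olfactory receptor genes were marked in 5 of 1092 cases (0.458%, Fisher's exact test, adjusted p = 2.39e-85) and vomeronasal receptor genes in 0 of 326 (adjusted p = 5.96e-28), both below their matched lists, which averaged 3.47% and 3.11%. Without replicate 1 the shares were 1.83% and 0.307%, and without replicate 2 they were 1.01% and 0.307%. The marked olfactory receptors, chosen after their values were seen, were Olfr1410, Olfr222, Olfr279, Olfr285 and Olfr95. Among CpG-rich promoters 1 vomeronasal gene remained, unmarked, and the call ended (Fisher's exact test, adjusted p = 1). Direction against other genes turned for the Polycomb genes under 5 alternatives and for the terminal products under 4, never past the threshold. The Polycomb share was 24.1% with either replicate left out. The housekeeping list passed without replicate 1 (5.0%, Fisher's exact test, adjusted p = 0.00512), with peaks at −log10 q of 5 or more (2.5%, adjusted p = 0.0297), with the pooled list (7.5%, adjusted p = 0.00801) and with a window of 2.5 kb (7.5%, adjusted p = 0.0380).

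The 14 lists above other coding genes were also all above the range of their CpG-matched random lists, 14 of 14. The adjusted p against matched lists was 0.0272 for muscle regulators, 0.00640 for kinase inhibitors and 0.00200 for broadly used facial factors. For the other 11 it was 0.000308, the smallest that the draws and the adjustment gave.

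**Figure D4:**
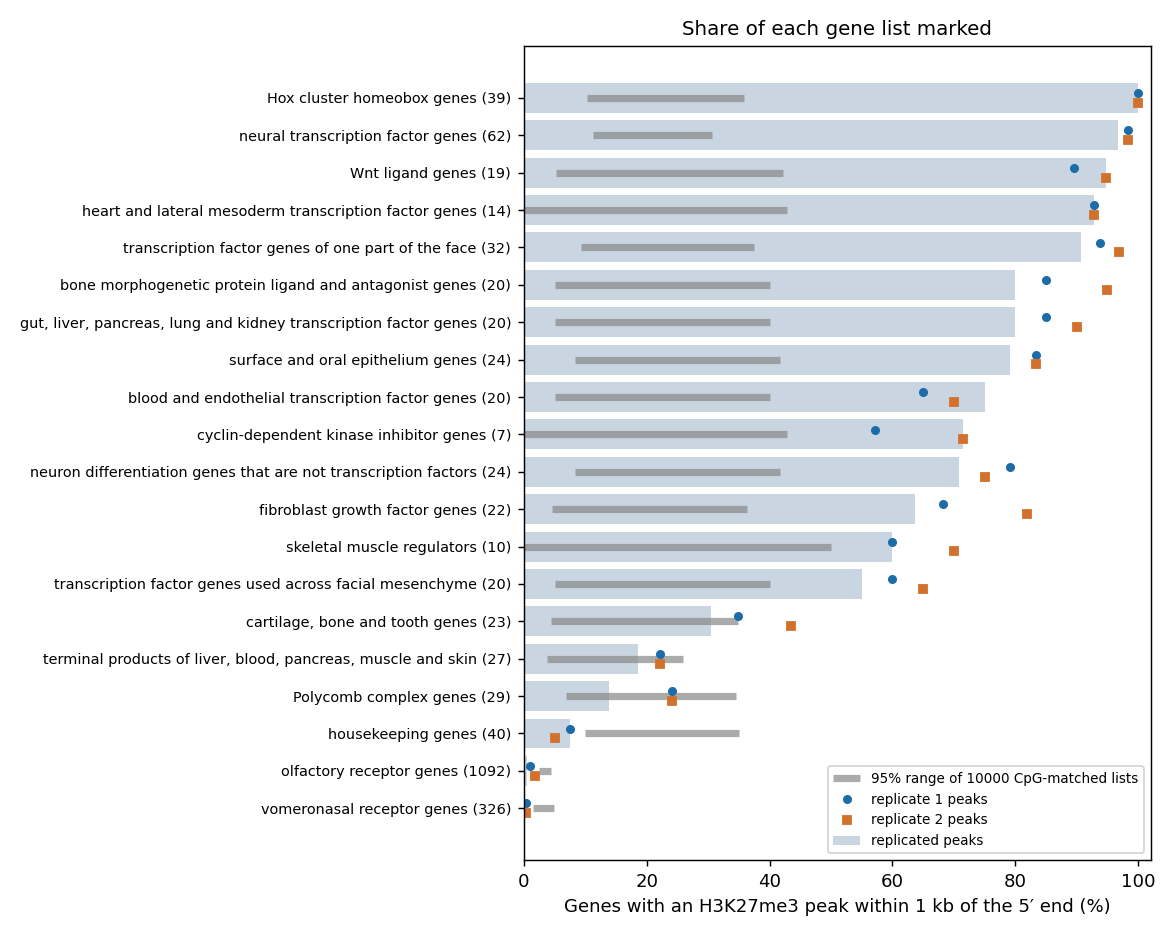
Percent of genes marked in each of the 20 gene lists, with bars for the replicated list, points for each replicate list and grey lines for the 95% range of 10000 CpG-matched random lists. The 14 lists from Hox genes (100%) to broadly used facial factors (55%) lie above their matched range.

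The 4 largest H3K27me3 domains held Hox genes. Joining peaks at most 3 kb apart gave 14028 domains, of which 504 had 10 kb or more covered. Without replicate 1 there were 46334 domains, 499 of that size, and without replicate 2 there were 32401, 392 of that size. Of the 504 large domains of the replicated list, 392 held the start of a coding gene, 531 genes in all, and 171 of those belong to the fixed short lists, a share that was not tested. The largest (chromosome 15, 102894015 to 103125013) held Hoxc13 to Hoxc4 with Hotair, a noncoding RNA gene of the cluster, and 207.8 kb were covered, with 189.5 kb in replicate 1 and 198.0 kb in replicate 2. Next came Hoxa1 to Hoxa13 with Evx1 (162.2 kb), Hoxb9 to Hoxb1 (127.4 kb) and Evx2 with the Hoxd genes (113.4 kb). The fifth (chromosome 7, 79494116 to 79622943, 107.0 kb) held Rhcg, Mir9-3 and its host gene, Mir9 being a neural microRNA. The sixth lay within Casz1 (chromosome 4, 148841398 to 148944490, 80.5 kb). Below these came Zic4 with Zic1 (63.3 kb), Nfix (62.0 kb), Hoxb13 (59.8 kb), Pax7 (56.8 kb), Dmbx1 (53.5 kb), Pdx1 with Cdx2 and Urad (52.3 kb), Tbx5 (50.5 kb), Nkx2-3 (48.0 kb), Pax2 (47.5 kb), Lhx2 (43.9 kb), Cdh22 (42.9 kb) and Wnt6 with Wnt10a (41.6 kb). The remaining 2 of the 20 largest held no coding start. They lay 52053 bp from Pax2 (51.7 kb) and at Mir9-1 (chromosome 3, 88191287 to 88248676, 49.4 kb). Every one of the 20 had covered bases in both replicate lists, and no test was applied.

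Chromosome X was among the chromosomes with the most H3K27me3 peaks per Mb. It had 21.5 replicated peaks per Mb against an autosome median of 13.1 (range 7.16 to 22.3), a ratio of 1.64 and rank 2 of 20. The ratio was 1.74 in replicate 1 and 1.38 in replicate 2. Covered length per Mb on X, against the autosome median, was 11.8 against 12.1 kb in the replicated list, 13.6 against 12.1 kb in replicate 1, 15.3 against 16.6 kb in replicate 2 and 26.3 against 20.6 kb in the pooled list. The number of replicate 2 peaks over that of replicate 1 was 1.08 on X and between 1.31 and 1.47 on the autosomes. In a comparison chosen after the chromosome values were seen, 113 of 301 CpG-rich gene starts on X were marked (37.5%) against 2314 of 10563 on the autosomes (21.9%). The difference was 15.6 percentage points (two-sided Fisher's exact test, p = 1.52e-09, adjusted over 13 tests 6.58e-09). It was 25.5 points without replicate 2 and 21.1 points without replicate 1, and X ranked highest of the 20 chromosomes in the replicated list and in both replicate lists. CpG-poor starts were marked in 12.7% of cases on X and 13.5% on the autosomes (Fisher's exact test, p = 0.593, adjusted p = 0.642). With peaks at −log10 q of 5 or more, CpG-poor starts were marked less often on X, 6.80% against 10.2% (Fisher's exact test, p = 0.00443, adjusted p = 0.00720).

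**Figure D5:**
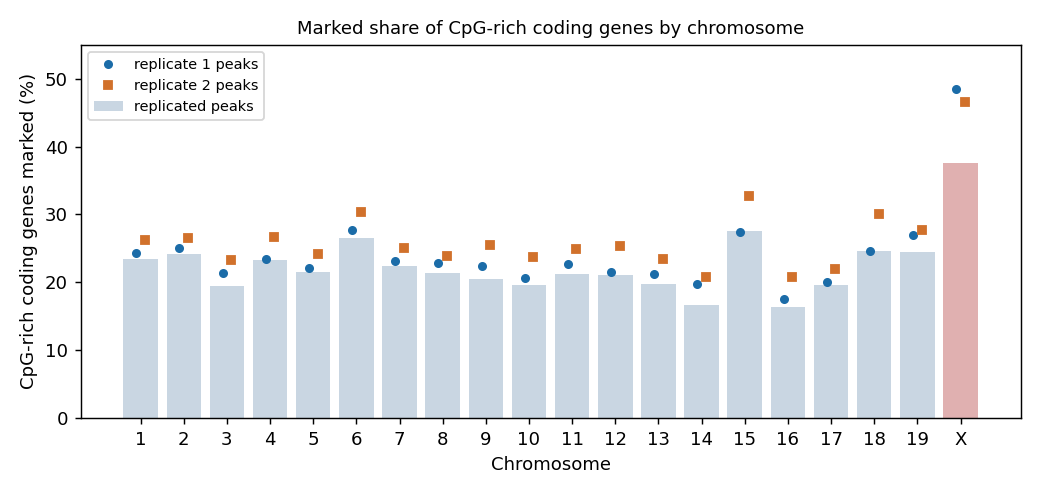
Percent of CpG-rich coding genes marked on each chromosome, with bars for the replicated list and points for each replicate list. CpG-rich starts on X stand at 37.5% in the replicated list, and the next chromosome, 15, stands at 27.6%.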

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

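Alternatives for the 33 results were set beforehand. A further 8 values for X, results and alternatives together, were chosen after the chromosome values were seen. Of 212 values under the alternatives fixed beforehand, 176 kept their direction and side of the threshold, moved by less than the spread between replicates or, for the counts of marked genes and broad domains, stayed within 1.5 times the reported count. In 12 a value without a test moved, in 8 a call appeared, in 5 a call ended, and in 11 the direction turned, never past the threshold. The calls for Hox genes, neural, regional facial, heart, endoderm and blood factors, epithelium and neuron genes, Wnt, fibroblast growth factor and bone morphogenetic protein genes held under all 8 alternatives, and those for olfactory receptors under the 7 that gave a value. No olfactory receptor has a CpG-rich promoter, so that alternative gave no value. With a reciprocal overlap of 50%, replicate overlap was 22.6% and 16.6%; with −log10 q of 5 or more in both lists 78.1% and 57.0%, with rho 0.527; with equal list lengths 43.9% and 38.6%. With at least 50% of the window covered, 2374 coding genes were marked, broadly used facial factors were at 20.0% (adjusted p = 0.314), kinase inhibitors at 28.6% (adjusted p = 0.216) and the regional minus neural difference at −21.6 points (adjusted p = 0.0178, all by Fisher's exact test); this window asks for more by construction. Among CpG-rich promoters muscle regulators were at 57.1%, skeleton genes at 80.0% and vomeronasal receptors at 0%, with 7, 5 and 1 genes left (Fisher's exact test, adjusted p = 0.0615, 0.0149 and 1). With the pooled list skeleton genes were at 47.8%, housekeeping at 7.5%, Polycomb genes at 31.0%, and the regional minus neural difference at 1.61 points. With −log10 q of 5 or more, kinase inhibitors were at 42.9%, housekeeping at 2.5% and terminal products at 11.1%. With a window of 2.5 kb housekeeping was at 7.5%, Polycomb genes at 24.1%, terminal products at 18.5% and the promoter ratio at 8.54. With any transcript start Polycomb genes were at 20.7%, terminal products at 18.5% and the regional minus neural difference at 0.101 points. With a replicate left out, skeleton genes ranged from 34.8% to 43.5%, housekeeping from 5.0% to 7.5%, Polycomb genes from 24.1% to 24.1%, terminal products from 22.2% to 22.2%, the promoter ratio from 7.32 to 8.26 and the X ratio from 1.38 to 1.74. Over the alternatives the adjusted p (Fisher's exact test, Benjamini-Hochberg) ran from 0.0149 to 0.805 for skeleton genes, from 0.00512 to 0.163 for housekeeping, from 0.00572 to 0.216 for kinase inhibitors, from 0.000343 to 0.0615 for muscle regulators and up to 0.314 for broadly used facial factors. For regional minus neural it ran from 0.0178 to 1. Except where the construction is named, the cause was not tested. Depth per library is unknown here, so a weak peak missing from a list is not shown to be absent from the tissue.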

Other observations

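The gene families, the Mir9 genes and both tests on X in this part were chosen only after results were seen; the tests on the replicates and the facial factors were set before their results were seen. Gene families taken from symbol stems of at least 10 genes were each compared with the other coding genes. Of 267 families, 31 were marked more often and 14 less often (two-sided Fisher's exact test, Benjamini-Hochberg over 267). Against 10000 random lists matched on promoter CpG density, 20 of the 31 were also higher and 9 of the 14 also lower (permutation test, adjusted p under the threshold of 0.05), and all families named here were among these. All 14 Nkx homeobox genes were marked (Fisher's exact test, adjusted p = 3.00e-09), 7 of them outside the fixed lists. Of 17 synaptotagmin (Syt) genes, which sense calcium for vesicle release, 13 were marked, and of 14 serotonin receptor (Htr) genes 11 were marked (Fisher's exact test, adjusted p = 8.33e-06 and 4.22e-05). Solute carriers (Slc) were marked in 113 of 371 cases (Fisher's exact test, adjusted p = 1.85e-07). Zinc finger protein (Zfp) genes were marked in 24 of 394 cases (6.09%, Fisher's exact test, adjusted p = 8.90e-10; 31 in the replicate 1 list and 40 in the replicate 2 list) and histone (Hist) genes in 0 of 67 (Fisher's exact test, adjusted p = 7.33e-05). Families share neighbours and ancestry, so their genes are not independent.

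Replicated peaks covered part or all of the surroundings of the 3 genes for the neural microRNA Mir9. They covered 98.1% of the 10 kb around Mir9-1, 100% around Mir9-3 and 41.2% around Mir9-2. Mir9-2 was covered to 24.6% in replicate 1 and 46.6% in replicate 2. No test was applied.

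Replicate 2 had 99718 peaks against 73355 in replicate 1. The tables argue against a GC bias that differs between the libraries, since the median GC of peaks seen in replicate 2 alone exceeded that of peaks in replicate 1 alone by 0.267 percentage points. Of the replicate 2 peaks at −log10 p of 10 or more, 97.1% overlapped a replicate 1 peak. This met the prediction set for peaks near the caller's threshold, but it does not show at which strength the excess lies. Replicate 2 had more peaks in every bin of −log10 p. There were 9938 against 6521 from 2 to 3, 49311 against 37481 from 3 to 5, and 33401 against 23375 from 5 to 10. Above these, there were 5549 against 5047 from 10 to 20 and 1519 against 931 at 20 or more. The excess was therefore not confined to peaks near the threshold, though most of the added peaks lay below −log10 p of 10. What put more peaks into the replicate 2 list stays open, as depth, the further files behind the lists and a difference between the pools were not tested. No biological explanation was tested.

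Facial transcription factor genes carried the mark in the tissue for which they were listed, though their expression was not measured here. The tables argue against weak peaks, since 95% of the 40 marked facial factor genes kept a peak at −log10 q of 5 or more. These were 29 of 29 marked regional factors and 9 of 11 marked broadly used factors. Most marked coding genes kept such a peak, 3202 of 3887, so the result does not set facial factors apart. A candidate explanation is that cells of parts of the face that do not use a gene carry the mark, since regional factors were marked more often than broadly used factors by 35.6 percentage points. Peaks beside the start may account for part of the pattern, and how far they set facial factors apart depends on the genes compared. A peak lay on the start itself in 60% of marked facial but 91.7% of marked neural factor genes. The difference was −31.7 points (two-sided Fisher's exact test, p = 0.000277, adjusted over 2 tests 0.000555). Among all marked coding genes the share was 61.8%, near that of the facial factors. A peak lay on the start in 5 of 11 marked broadly used factors and 19 of 29 marked regional factors. Other lists varied. The counts were 36 of 39 for Hox, 12 of 13 for heart, 15 of 16 for endoderm and 17 of 18 for Wnt genes. They were 9 of 15 for blood, 9 of 16 for bone morphogenetic protein and 9 of 14 for fibroblast growth factor genes. These counts per list were not tested. Which cells carry the mark cannot be read from whole tissue and stays open.

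CpG-rich gene starts on X were marked more often than those on the autosomes. The tables argue against peaks near the caller's threshold as the whole account, since with peaks at −log10 q of 5 or more the excess was 11.1 percentage points (two-sided Fisher's exact test, p = 5.84e-06, adjusted over 13 tests 1.90e-05), against 15.6 with all replicated peaks. The inactive X of female cells is a candidate explanation. Families taken as broadly used included Rpl, Med and Usp. Their CpG-rich genes were marked in 6 of 27 cases on X and 24 of 660 on the autosomes. The excess on X was 18.6 points (Fisher's exact test, p = 0.000644, adjusted p = 0.00120). These families were picked after totals per family had been seen. Any cause of more peaks at CpG-rich starts across X would give such an excess, so it does not single out the inactive X. That excess was 7.93 points and no longer past the threshold with peaks at −log10 q of 5 or more (Fisher's exact test, p = 0.0631, adjusted p = 0.0912). Genes known to escape X inactivation were marked in 0 of 5 cases against 113 of 296 other CpG-rich genes on X, too few to decide (Fisher's exact test, p = 0.161, adjusted p = 0.209), and the sexes were not separated, so the explanation stays open.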
